A study of Rattus norvegicus with 12 samples.

How the data were processed

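The values used here were the expression values that the authors deposited for 12 Affymetrix Rat Genome 230 2.0 arrays, 3 for each of 4 groups. Per the labels they were MAS5 signals, and the deposited values were log2 signals with a lowest value of 0 on every array. The linear signals behind them had a 2% trimmed mean of 500 on each array, as MAS5 scaling gives. No centring between probe sets or between arrays was present in the deposited values. The MAS5 version was not given in the sources used here. The deposited report file gave MAS5 scaling factors, which are a score, between 1.84 and 3.29 with a median of 2.28. The same deposited file gave the percent of probe sets called present, between 44.4 and 58.0 with a median of 55.2. Its array names occurred in no sample label, so these values were used only as ranges over the 12 arrays. Scanned images were not analysed here.

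Signals were taken back to the linear scale, each array was scaled again to a 2% trimmed mean of 500, and 16 was added before taking log2. This offset keeps differences between near-background signals small. Probe sets were kept where the signal was at least 100 in at least 3 arrays of a fit. Of 31099 probe sets, 20832 named 1 gene, 436 named several genes and 9831 named none, and 57 of all probe sets were controls. Symbols were compared with the RefSeq gene table of the assembly GRCr8, which matched 20764 of the 20832 probe sets and changed 0 symbols. That table also gave the chromosome of each gene, and no coordinates were used. A gene with several kept probe sets was represented by the set with the highest mean signal, which applied to 2302 genes of the fit of the ES cell arrays. Probe sets with several names were left out of gene tests, and probe sets with none were tested apart. Genes of which a close copy exists, such as Uty beside its X-linked relative, were treated as uncertain.

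Differences were tested with limma 3.58.1 in R 4.3.3, with moderated variances that follow a trend on mean signal. Comparisons among ES cells used the 9 ES cell arrays and 9324 genes. Round sperm cells are freshly isolated cells of another kind, whose spread need not be that of cultured ES lines. Comparisons with round sperm cells used all 12 arrays and 10539 genes, so that the 4 groups shared a filter and an estimate of the spread there. RahES stands for the mean of the lines RAH-6 and RAH-2, each line with equal weight. A gene was called changed at a Benjamini-Hochberg adjusted p below 0.05 and an absolute log2 fold change of at least 1. The replicate numbers of the labels were not entered, since the labels do not say that they tie arrays of different groups together. Where every array of one group was below 100, only a lower bound of the fold was reported, taken between 100 and the group above it. Lists that hold such genes were given a second median with those genes at their bound.

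A set of 28 gene lists with 784 entries was written from general knowledge, of which 622 entries were on the array. They cover pluripotency, germ cell stages, imprinted genes, markers of other cell types, signalling targets, metabolism and the cell cycle. Lists were tested with camera of limma at its preset correlation of 0.01, adjusted over the 28 lists of a comparison. Each list was tested again with its correlation estimated from the data, which is stricter for genes that move together. It could also be stricter where the estimate was below 0.01. For round spermatid genes in RahES against round sperm cells the estimate was -0.00160, and the camera p rose from 6.9e-13 to 3.6e-05. A call lost in this second test therefore does not by itself show that genes move together. Members called after adjustment over the list alone were counted too, and these counts equalled the overall counts unless both are printed. Each chromosome was tested in the same way as a list. Pairs of comparisons with a common control were set beside 100 draws of simulated groups without change against the same controls.

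Genes named in the text followed 1 rule. It took the 8 largest rises and the 8 largest falls among called genes whose arrays did not overlap between the groups, for RahES against DA5-3, RAH-6 against RAH-2, and each kind of ES cell against round sperm cells. It added up to 4 called members of each described list with the smallest adjusted p. Xist, Igf2, H19, Meg3, Snrpn, Peg3, Mest, Pou5f1, Nanog, Sox2, Prm1 and Tnp1 were looked up in every comparison. Each single line against DA5-3 was described by the genes named for RahES against DA5-3. Members of a list that were not called are given only as values. The design, the lists, this rule and all alternatives but 1 were chosen before the data were examined. The exception, added later, leaves out DA5-3 replicate 1, RAH-2 replicate 2 and round sperm replicate 1. Control probe sets were extreme on DA5-3 replicate 1 and round sperm replicate 1. On RAH-2 replicate 2 the hybridization control cre read 27272, against 25438 and 25514 on the other RAH-2 arrays. Its 3' to 5' ratios were not raised. That array stood apart in fibroblast markers, at 23.2% of the DA5-3 level against 5.84 and 7.98%, so its removal is no pure quality filter.

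The code was tested on simulated data with 100 genes at each fold. Among genes given a 2-fold difference, 44 to 57% were called in the right direction, since the size limit equals the true change, while 91 to 98% passed the adjusted p alone. Of genes given a 4-fold difference 99 to 100% were called, and 0 to 4 of the unchanged genes were. A list given a shift was found in all 6 comparisons. Alternatives covered other offsets, filters, scalings, ways to join probe sets, variance models, sets of arrays, treatments of the lines and of the replicate number, and the removal of each array in turn. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.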

Results

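Gene expression was measured on 12 arrays from inbred Dark Agouti rats. RAH-6 and RAH-2 are androgenetic haploid embryonic stem (ES) cell lines, together called RahES, DA5-3 is a diploid ES cell line, and round sperm cells are freshly isolated haploid germ cells. Each of the 4 groups had 3 biological replicates, and the number of arrays limits the precision. The probe sets of the array named 14218 genes. Between 41.4 ± 1.08% (SD, n = 3, round sperm cells) and 48.6 ± 0.384% (RAH-6) of probe sets had a signal of at least 100, against 48.5 ± 0.328% in DA5-3 and 47.7 ± 0.599% in RAH-2. None of the 66 pairs of arrays held identical values. Replicates were close to each other, with Pearson r from 0.987 to 0.989 in DA5-3, 0.988 to 0.992 in RAH-2, 0.990 to 0.991 in RAH-6 and 0.984 to 0.985 in round sperm cells. Arrays of RAH-2 and RAH-6 correlated at 0.982 to 0.987, and DA5-3 with them at 0.953 to 0.965, whereas ES cells and round sperm cells reached only 0.211 to 0.225. In the principal component plots, PC1 separated ES cells from round sperm cells with 93.8% of the variance, and among ES cells PC1 separated DA5-3 from RahES with 68.0%.

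**Figure D1:**
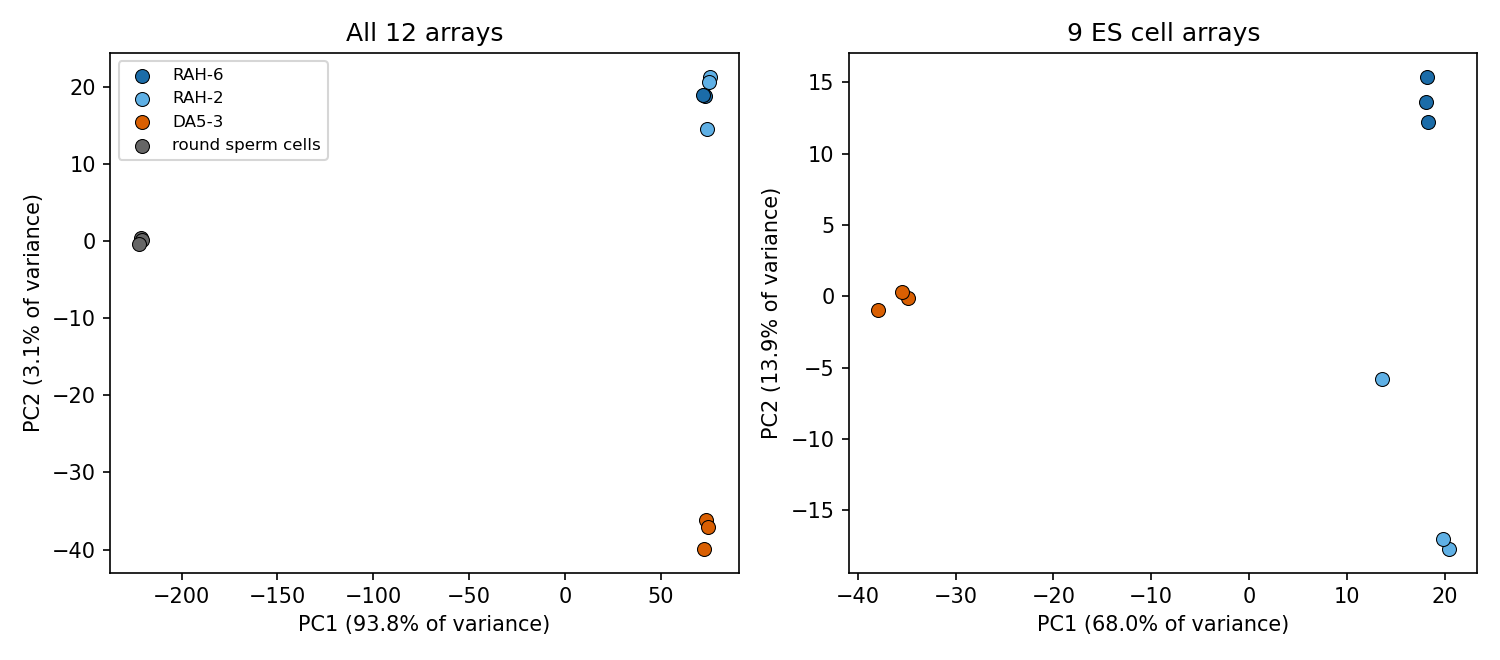
Principal components of log2 signals. Left, all 12 arrays (PC1 93.8%, PC2 3.1% of the variance). Right, the 9 ES cell arrays (PC1 68.0%, PC2 13.9%). Each point is 1 array, n = 3 per group.

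The ratio of 3' to 5' signal of the Gapdh control probe sets, which grows with RNA degradation, differed between the groups. It averaged 1.14 in RAH-6 (range 1.11 to 1.16, n = 3), 1.26 in RAH-2 (1.23 to 1.30), 1.47 in DA5-3 (1.35 to 1.69) and 2.18 in round sperm cells (1.78 to 2.48). For actin the ratio was 3.09, 4.36, 6.19 and 4.09 in the same order. Mean ratios of both kinds rose from RAH-6 to RAH-2 to DA5-3, whereas round sperm cells were highest for Gapdh but not for actin. The control probe sets dap and cre also separated DA5-3 from both RahES lines without overlap. For dap, DA5-3 read 2222 to 3159, RAH-6 799 to 1277 and RAH-2 1334 to 1461. For cre, DA5-3 read 30241 to 36011, RAH-6 23036 to 25115 and RAH-2 25438 to 27272. Only 1 diploid line was measured, so ploidy, origin, line and sample processing cannot be told apart. The p-values measure the spread between cultures of these lines. Fold changes below are log2 ± standard error and signals are means ± SD in MAS5 units, with adjusted p from limma. A fold with a group mean below 100 rests on signals near background.

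How the haploid androgenetic lines differ from the diploid line was asked with RahES (n = 6) against DA5-3 (n = 3). The collagen genes Col1a1, Col5a2 and Col1a2 were far lower in RahES: Col1a1 fell by 4.39 ± 0.37 (321 ± 178 against 5989 ± 173, adjusted p = 7.8e-07), Col5a2 by 4.37 ± 0.50 (882 ± 595 against 12486 ± 342) and Col1a2 by 4.36 ± 0.43. The RNA-binding protein gene Rbms3 fell by 3.94 ± 0.33, the matrix genes Vcan by 3.81 ± 0.34 and Ccdc80 by 3.79 ± 0.28, and the mesenchymal cadherin gene Cdh11 by 3.75 ± 0.54. Rbms3 and Vcan averaged 65.2 and 62.0 in RahES and passed 100 only on RAH-2 replicate 2. The nuclear receptor gene Nr2f2, at 482 ± 109 in DA5-3 and below 100 on every RahES array, was at least 4.73-fold lower. Among genes higher in RahES, natriuretic peptide B (Nppb) rose by 3.47 ± 0.10 (1815 ± 544 against 144 ± 16.3, adjusted p = 8.6e-11), the thyrotropin-releasing hormone precursor Trh by 3.14 ± 0.10, S100a1 by 3.22 ± 0.31, Egr2 by 3.21 ± 0.16 and the X-linked Armcx4 by 2.75 ± 0.09. S100a16 (347 ± 69.5), the melanocyte gene Mlana (325 ± 35.7) and the peptide hormone gene Adm (640.2 ± 354) were below 100 on all DA5-3 arrays and at least 3.41-fold, 3.24-fold and 5.55-fold higher in RahES. In all, 346 genes were higher and 268 lower, 6.59% of 9324 genes, and for 202 of them only a bound of the fold was known. Without the limit on size, 2923 and 2420 genes passed the adjusted p, and the median over all genes was 0.0316.

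Markers of fibroblasts, the usual feeder cells, had the largest median shift of the 28 lists. Of 22 measured, 14 were lower and 1 higher, with a median of -1.94 (-1.83 with bounds, camera adjusted p = 0.00122). The adjusted p = 0.417 with an estimated correlation, so the list was not called when its genes were allowed to move together. Besides the collagens, smooth muscle actin Acta2 fell by 2.61 ± 0.21 (320.4 ± 108 against 1938 ± 232), Col5a1 by 1.96 ± 0.08 and the chemokine gene Cxcl12 by 1.74 ± 0.12. The matricellular gene Ccn1 was the exception and rose by 1.83 ± 0.07 (7358 ± 877 against 2050.2 ± 65.9). Within RahES these markers were uneven, since RAH-2 replicate 2 read 543 for Col1a1 and the other RAH-2 arrays 89.2 and 123. Extraembryonic endoderm markers had a median of -0.48 with 3 higher and 6 lower of 20 (-0.47 with bounds, adjusted p = 0.0413, and adjusted p = 0.339 with an estimated correlation). Among them Pdgfra fell by 2.68 ± 0.22 and Fxyd3 by 1.41 ± 0.11, while the apolipoprotein gene Apoa2 rose by 1.39 ± 0.12 and the collagen chaperone gene Serpinh1 by 1.18 ± 0.13. The call of this list ended without DA5-3 replicate 1 (adjusted p = 0.0572), DA5-3 replicate 2 (0.0719) or RAH-6 replicate 1 (0.0540), and that of Serpinh1 without DA5-3 replicate 1. Of 9 measured genes of the Sertoli cell list, 3 were lower, namely the intermediate filament gene Vim by 2.94 ± 0.39 (857 ± 488 against 5366 ± 310.4), Inhbb by 2.41 ± 0.26 (mean of 86.2 in RahES) and Gata4 (at least 1.47-fold), with a median of -0.09 and adjusted p = 0.168. Mesoderm markers had 1 of 5 lower (Twist1, at least 2.52-fold, median -0.08, adjusted p = 0.383). Neural markers had 1 of 6 higher (Dcx, at least 2.28-fold, median 0.32, adjusted p = 0.286), and trophoblast markers 1 of 14 higher (Rhox9, at least 1.37-fold, adjusted p = 0.892) with a median of -0.07 and a mean of 0.07. Leydig cell genes had 1 of 3 lower (Akr1c14, -1.53 ± 0.11), where the median of 0.28 and the mean of -0.28 differed in sign (adjusted p = 0.986). The 2 measured genes of blood and macrophages included Laptm5, which rose by 1.12 ± 0.08 (list median 0.60, adjusted p = 0.292).

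**Figure D2:**
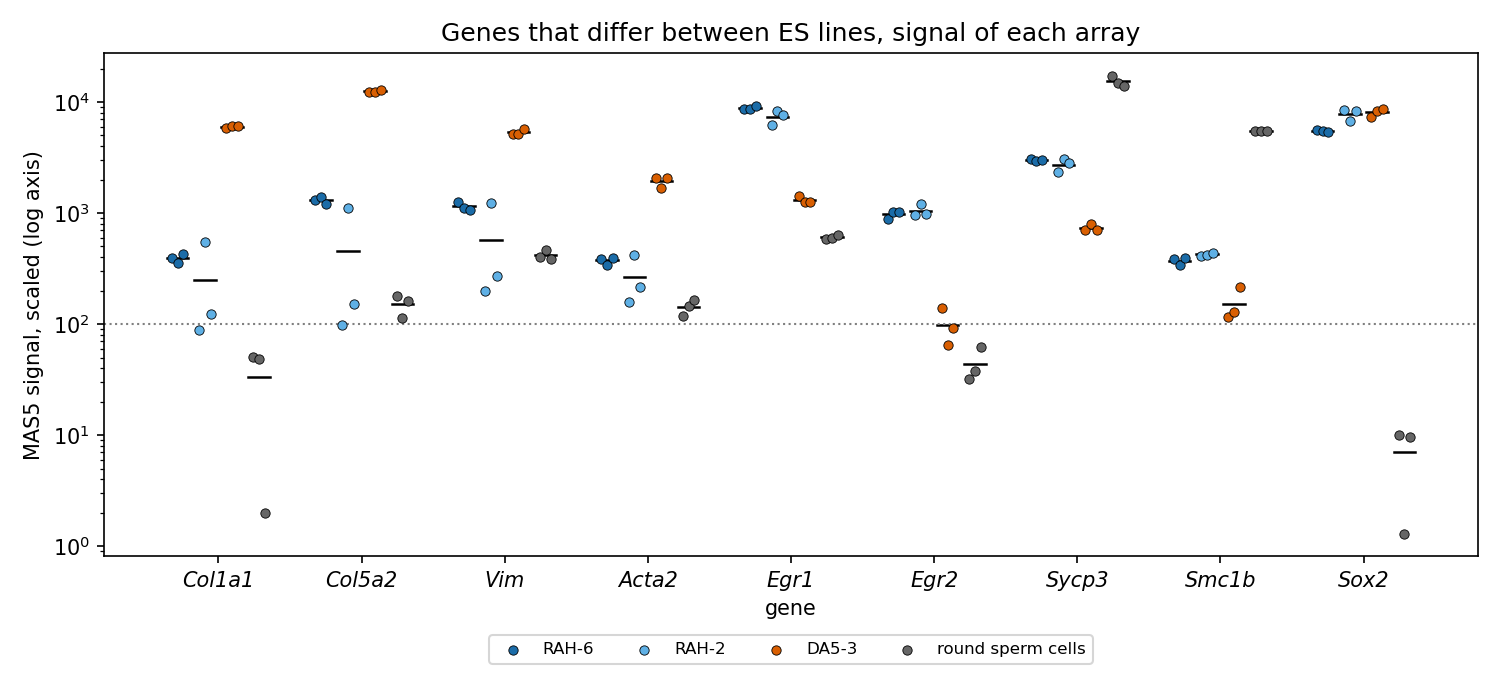
Signals of Col1a1, Col5a2, Vim, Acta2, Egr1, Egr2, Sycp3, Smc1b and Sox2 by group. Points are arrays, bars are group means (n = 3), the axis is logarithmic, and the dotted line marks a signal of 100.

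Imprinted genes, which at least in some tissues are expressed from only 1 parental copy, changed in both directions in RahES, whose genome is paternal. Paternally and maternally expressed here name the lists, and which copy was used in these cells was not measured. Among paternally expressed genes the growth factor gene Igf2 fell by 3.32 ± 0.14 (271 ± 58.2 against 2793 ± 147, adjusted p = 1.6e-09). This rests on a single probe set. The other Igf2 probe sets were near background in all ES lines, with DA5-3 means of 14.4, 36.4 and 6.03. In the same list Nnat rose by 1.42 ± 0.08 (1455 ± 95.9 against 537 ± 80.3), the zinc finger gene Plagl1 rose by 1.40 ± 0.23 (740.5 ± 285 against 252 ± 49.1), and Nap1l5 was at least 1.44-fold lower. Among maternally expressed genes the growth regulator gene Grb10 fell by 1.93 ± 0.11 (203 ± 42.0 against 815 ± 133, adjusted p = 3.5e-08), the cell cycle inhibitor gene Cdkn1c by 1.21 ± 0.11 and the ubiquitin ligase gene Ube3a by 1.00 ± 0.07, at the limit of size and below it without DA5-3 replicate 1, RAH-2 replicate 2 or RAH-6 replicate 3. The cation transporter gene Slc22a3 was at least 2.00-fold higher. The maternally expressed RNAs H19 (3148 ± 711 against 3735 ± 116, -0.28 ± 0.06) and Meg3 (1517 ± 314 against 2014 ± 263, -0.42 ± 0.11) stayed abundant and were not called. Mest, at 555 ± 93.1 against 747 ± 65.0, was not called either (-0.43 ± 0.11). Of 22 maternally expressed genes 1 was higher and 5 lower (median -0.21, adjusted p = 0.168), and of 17 paternally expressed genes 2 were higher and 2 lower (median -0.15, adjusted p = 0.326). Snrpn averaged 61.9 in RAH-6, 75.4 in RAH-2 and 116 in DA5-3, too low to be tested, and no probe set was named for Peg3.

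**Figure D3:**
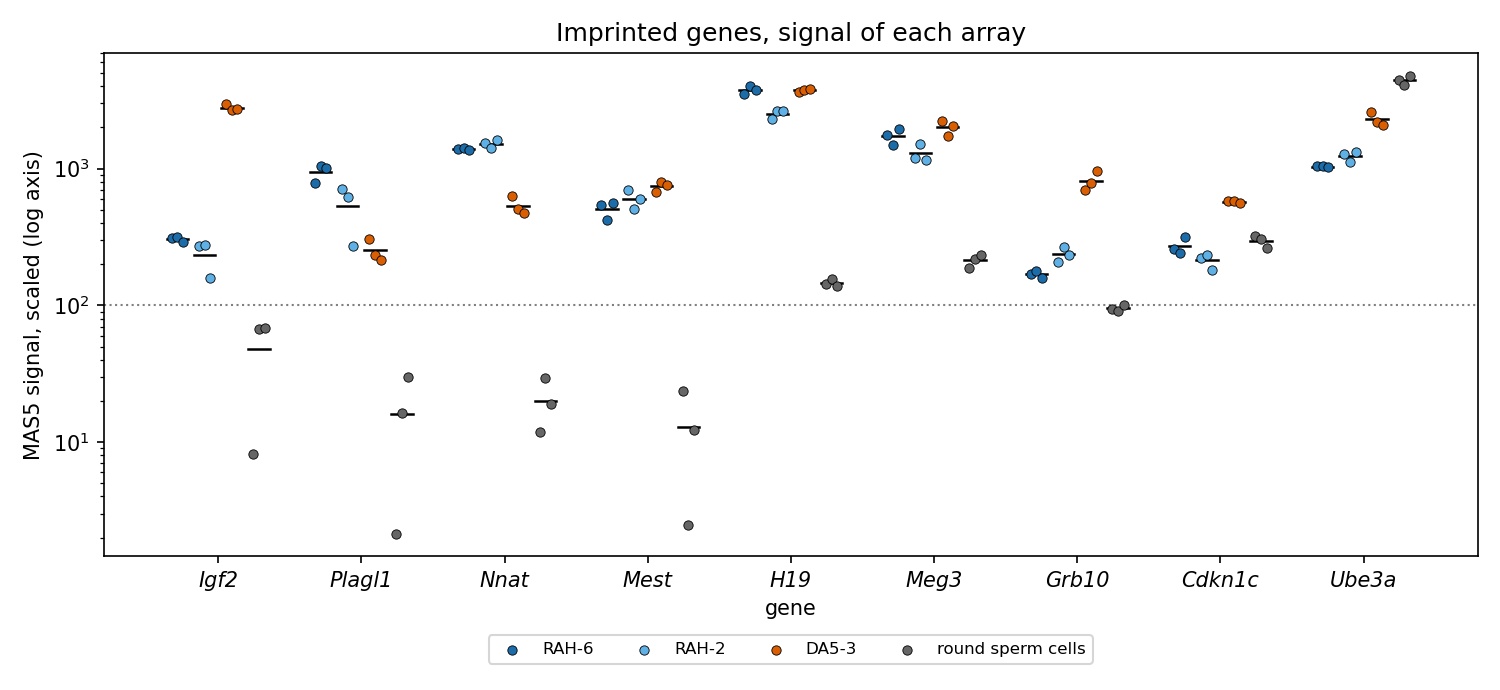
Signals of imprinted genes by group: Igf2, Plagl1, Nnat and Mest (listed as paternally expressed) and H19, Meg3, Grb10, Cdkn1c and Ube3a (listed as maternally expressed). Points are arrays, bars are group means (n = 3), the axis is logarithmic, and the dotted line marks a signal of 100.

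Of 21 genes of naive pluripotency 0 were called by limma in RahES against DA5-3, although 16 passed the adjusted p alone. The list had a median of -0.16 (adjusted p = 0.0706, and adjusted p = 0.339 with an estimated correlation). At the preset correlation it passed the threshold without the filter on low signals (-0.21, adjusted p = 0.0444) and with a filter at 200 (-0.24, adjusted p = 0.03549). Sox2 read 6640.0 ± 1454 against 8078 ± 721 (-0.31 ± 0.07, adjusted p = 0.00322), and no probe set was named for Pou5f1 or Nanog. Genes of the primed epiblast were lower in 5 of 10 cases, with Sox4 falling by 2.45 ± 0.19, Cdh2 by 2.30 ± 0.16, Eomes by 1.51 ± 0.09 and the DNA methyltransferase gene Dnmt3a by 1.37 ± 0.15 (median -0.85, adjusted p = 0.106). Targets of the ERK kinase pathway, which the 2i medium inhibits, had a median of 0.50 with 5 higher and 1 lower of 17 (0.31 with bounds, adjusted p = 0.0253, and adjusted p = 0.293 with an estimated correlation). The early-response genes Egr1 (8093 ± 1071 against 1310.5 ± 96.6) and Ier2 rose by 2.60 ± 0.08 and 1.05 ± 0.05, whereas cyclin D1 (Ccnd1) fell by 1.98 ± 0.07. Of 25 listed germline genes that depend on DNA methylation for silencing, 8 were measured. Genes high only in the 6 RahES arrays pass the filter on signal more easily than genes high only in the 3 DA5-3 arrays. All 8 measured genes were above DA5-3, and 3 were called higher (median 0.71, adjusted p = 0.0121, and adjusted p = 0.293 with an estimated correlation). These were the synaptonemal complex gene Sycp3, up 1.95 ± 0.07 (2872 ± 273 against 732 ± 54.4), the meiotic cohesin gene Smc1b, up 1.33 ± 0.15 (398 ± 34.9 against 153 ± 53.4), and Taf7l, at least 2.21-fold higher. Genes of the DNA methylation machinery had 2 of 19 lower, Dnmt3a and the dioxygenase gene Tet3 (-1.43 ± 0.07), with a median of -0.02 (adjusted p = 0.214).

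Cholesterol and fatty acid synthesis genes were lower as a list, with 3 of 21 called, a median of -0.26 and adjusted p = 0.00122 (adjusted p = 0.293 with an estimated correlation). Scd fell by 1.19 ± 0.06, Fasn by 1.08 ± 0.06 and Mvd by 1.02 ± 0.08, the last below the limit of size without DA5-3 replicate 1, RAH-2 replicate 1 or RAH-6 replicate 1. In glycolysis Pfkp rose by 1.47 ± 0.04 and Pdk1 by 1.29 ± 0.05, the only 2 of 23 genes called, while the median of -0.04 and the mean of 0.22 differed in sign (adjusted p = 0.524). Plk2 rose by 1.68 ± 0.06 among 19 p53 targets (median 0.28, adjusted p = 0.0550). Tekt2, a sperm tail gene, rose by 1.35 ± 0.09 among 7 round spermatid genes (median 0.33, adjusted p = 0.146). Of 12 spermatocyte genes only Sycp3 and Smc1b were higher (median 0.25, with bounds 0.13, adjusted p = 0.286). Spermatogonia genes had 2 of 7 higher, Itga6 (1.51 ± 0.09) and Sohlh1 (97.7 ± 30.1 against 23.3 ± 14.1), with adjusted p = 0.422. Among 8 Wnt targets Tcf7 rose by 1.74 ± 0.10 and Ccnd1 fell (median -0.26, adjusted p = 0.286). No gene was called among 31 of DNA replication (median -0.10, adjusted p = 0.410), 29 of mitosis (median 0.05, adjusted p = 0.907), 13 linked to the cell cycle of haploid cells (median -0.00261, adjusted p = 0.751), 39 of oxidative phosphorylation (median 0.07, adjusted p = 0.286), 14 housekeeping genes (median -0.10, adjusted p = 0.524) or 6 genes of X inactivation and the Y chromosome (median -0.23, adjusted p = 0.390). Xist was near background in both, 91.4 ± 37.1 against 147 ± 26.0. The 305 X-linked genes had a median of 0.0434 and autosomal genes 0.0316, a difference of 0.0118 (adjusted p = 0.962), although 7.54% of them were called higher against 3.58% of autosomal genes.

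Whether both haploid lines shared these differences was asked by setting each line alone against DA5-3 (n = 3 and 3). In RAH-2 the collagen genes Col5a2, Col1a2 and Col1a1 fell by 5.49 ± 0.58, 4.96 ± 0.50 and 4.90 ± 0.43, Cdh11 by 4.56 ± 0.63, Ccdc80 by 4.34 ± 0.32, Vcan by 4.15 ± 0.39 and Rbms3 by 4.14 ± 0.38, the last 3 with RAH-2 means of 90.2, 49.4 and 60.3 and only replicate 2 above 100. Adm was at least 9.54-fold, Mlana at least 3.04-fold and S100a16 at least 2.96-fold higher, and Nr2f2 at least 4.73-fold lower. Egr2 rose by 3.26 ± 0.18, Trh by 3.18 ± 0.11, Nppb by 3.09 ± 0.12, S100a1 by 2.66 ± 0.35, Armcx4 by 2.65 ± 0.11 and Egr1 by 2.47 ± 0.09. Igf2 fell by 3.52 ± 0.16 (234.9 ± 67.1 against 2793 ± 147, adjusted p = 6.0e-09), Grb10 by 1.71 ± 0.13 and Cdkn1c by 1.37 ± 0.12, Nnat rose by 1.48 ± 0.09, and Slc22a3 was at least 1.69-fold higher. Plagl1 (0.94 ± 0.27) and Ube3a (-0.87 ± 0.08) were not called in RAH-2. Xist, at 60.0 ± 10.8 and below 100 on every RAH-2 array, was at least 1.45-fold lower, a call that ended without DA5-3 replicate 1 or RAH-2 replicate 3, while H19 (-0.56 ± 0.07), Meg3 (-0.63 ± 0.12), Mest (-0.31 ± 0.13) and Sox2 (-0.05 ± 0.08) were not called. In all, 312 genes were higher and 297 lower. The share of higher genes among those called was 51.2%. It was 44.5% with median centring, 44.7% with an offset of 64 and 47.2% without the filter, so the balance depends on the processing. Fibroblast markers had a median of -2.15 (-1.89 with bounds), with 1 higher and 15 lower, or 16 lower adjusted over the list alone (camera adjusted p = 3.3e-05, and adjusted p = 0.355 with an estimated correlation). Extraembryonic endoderm markers had a median of -0.62 (adjusted p = 0.00117) and methylation-dependent germline genes a median of 0.77 (adjusted p = 0.00488), each with adjusted p = 0.229 with an estimated correlation. Targets of p53 had a median of 0.29 (adjusted p = 0.0420, 0.0569 without DA5-3 replicate 2, and adjusted p = 0.229 with an estimated correlation). Not called in RAH-2 were the ERK targets (median 0.48, with bounds 0.32, adjusted p = 0.0644) and cholesterol synthesis genes (0 of 21 called, median -0.12, adjusted p = 0.0978).

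In RAH-6 the genes named as called in RAH-2 moved in the same directions, with the collagen genes, Ccdc80 and Cdh11 less far below DA5-3. Of these only Col5a2 and Ccdc80 were called between the lines, and the RAH-2 arrays were uneven for both. Col1a1 fell by 3.89 ± 0.43, Col1a2 by 3.76 ± 0.50, Col5a2 by 3.24 ± 0.58, Ccdc80 by 3.24 ± 0.32 and Cdh11 by 2.93 ± 0.63. Rbms3 was at least 11.2-fold, Vcan at least 9.69-fold and Nr2f2 at least 4.73-fold lower. Nppb rose by 3.85 ± 0.12, S100a1 by 3.79 ± 0.35, Egr2 by 3.15 ± 0.18, Trh by 3.09 ± 0.11, Armcx4 by 2.84 ± 0.11 and Egr1 by 2.74 ± 0.09, and S100a16, Mlana and Adm were at least 3.93-fold, 3.45-fold and 3.22-fold higher. Igf2 fell by 3.12 ± 0.16 (306 ± 12.6 against 2793 ± 147, adjusted p = 1.2e-08), Grb10 by 2.16 ± 0.13, Ube3a by 1.13 ± 0.08 and Cdkn1c by 1.04 ± 0.12. Plagl1 rose by 1.85 ± 0.27 and Nnat by 1.36 ± 0.09, and Slc22a3 was at least 2.38-fold higher. Values for Xist (-0.23 ± 0.20), H19 (0.01 ± 0.07), Meg3 (-0.21 ± 0.12), Mest (-0.55 ± 0.13) and Sox2 (-0.56 ± 0.08) were not called. In all, 443 genes were higher and 268 lower. Cholesterol synthesis genes had a median of -0.44 (adjusted p = 3.1e-05, and adjusted p = 0.210 with an estimated correlation), fibroblast markers -1.70 (-1.60 with bounds, adjusted p = 0.01496, and adjusted p = 0.554 with an estimated correlation). Naive pluripotency genes had a median of -0.39 (adjusted p = 0.01496), ERK targets 0.75 (0.49 with bounds, adjusted p = 0.01496) and methylation-dependent germline genes 0.70 (adjusted p = 0.0222), each with adjusted p = 0.241 with an estimated correlation. Not called in RAH-6 were extraembryonic endoderm markers (3 higher and 2 lower of 20, median -0.38, adjusted p = 0.272) and p53 targets (median 0.23, adjusted p = 0.118).

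Both lines had 248 genes higher and 206 lower than DA5-3 in common, and 0 genes called in opposite directions. Independent calls would give 14.8 and 8.54 shared genes. The fold changes of the lines correlated at r = 0.879, against 0.500 in simulated groups without change that share the DA5-3 arrays, in which 0 calls were shared. Their covariance was 0.293 against 0.00845 in the simulation, a difference of 0.285. The simulated groups held only the spread between cultures and no difference between lines. The excess over them therefore cannot tell a trait shared by the haploid lines from a trait of the DA5-3 line. Part of the overlap above that of independent calls may come from the shared controls, and 3 control arrays cannot be split into separate sets.

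The haploid lines were then compared with each other, RAH-6 against RAH-2 (n = 3 and 3). The collagen gene Col5a2 was higher in RAH-6, up 2.25 ± 0.58 (1308 ± 103 against 455 ± 574, adjusted p = 0.0183), as was the matrix protease gene Mmp2, up 1.63 ± 0.35 (adjusted p = 0.00784). The melanosome gene Pmel rose by 1.73 ± 0.12 (1181 ± 34.7 against 348 ± 45.7, adjusted p = 9.7e-06). Phlda2, an imprinted gene, was at least 1.99-fold, S100g at least 1.41-fold and Art1 at least 1.13-fold higher. Nrk (76.5 ± 14.3 against 6.71 ± 1.04) and Hs3st1 (73.3 ± 15.0 against 16.1 ± 23.5) were called higher at signals below 100. The homeobox gene Hoxa9 fell by 1.68 ± 0.12 (235 ± 25.2 against 796 ± 132, adjusted p = 9.7e-06), Hoxa7 was at least 1.17-fold lower, and the antisense RNA Hoxa11-as was called lower (12.7 ± 15.9 against 100.4 ± 8.93). Adm fell by 1.52 ± 0.11 (322 ± 6.97 against 958 ± 99.9), the stress-response gene Ddit4 by 1.35 ± 0.10 and Ankrd37 by 1.35 ± 0.11. The growth factor carrier gene Fgfbp3 fell by 1.39 ± 0.14, and Mtnap1 was called lower at mean signals below 100 (25.7 ± 8.41 against 86.6 ± 38.3). In all, 56 genes were higher and 18 lower, 0.794% of those tested. Without RAH-2 replicate 2 there were 110 higher genes, and without RAH-2 replicate 3 there were 37, while without RAH-2 replicate 1 there were 11 lower genes. The calls of Col5a2, Hs3st1, Mtnap1 and Hoxa7 ended without RAH-2 replicate 3, and those of Col5a2, Hs3st1 and Mtnap1 also without RAH-2 replicate 1 or, for Col5a2 and Mtnap1, a single RAH-6 array. H19 (3766 ± 283 against 2529.6 ± 195, 0.57 ± 0.07), Meg3 (0.42 ± 0.12), Igf2 (0.40 ± 0.16), Xist (0.87 ± 0.20), Mest (-0.24 ± 0.13) and Sox2 (-0.51 ± 0.08) were not called.

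Fibroblast markers were again the list with the largest median between the haploid lines, 0.84 (0.63 with bounds), with 5 of 22 higher in RAH-6, or 9 adjusted over the list alone. Among them S100a4 rose by 1.38 ± 0.41 (387 ± 33.2 against 185 ± 185) and Tagln was at least 1.22-fold higher. The list had adjusted p = 3.9e-04, and adjusted p = 0.524 with an estimated correlation. Of 20 extraembryonic endoderm markers 17 were higher in value in RAH-6 and 2 were called, the matrix protein gene Sparc (1.14 ± 0.28) and the plasminogen activator gene Plat (1.12 ± 0.21), with a median of 0.57 (0.56 with bounds, adjusted p = 7.5e-06, and adjusted p = 0.0626 with an estimated correlation). Vim rose by 1.45 ± 0.45. The calls of Sparc, Plat, Tagln, S100a4 and Vim ended without RAH-2 replicate 1, and those of Sparc, S100a4 and Vim also without RAH-2 replicate 3. The cholesterol synthesis list was lower in RAH-6, 20 of 21 values being negative with none called (median -0.30, adjusted p = 1.2e-07), and Wnt targets were negative in 8 of 8 cases (median -0.56, with bounds -0.46, adjusted p = 2.5e-04). Each of these lists had adjusted p = 0.0626 with an estimated correlation. Glycolysis genes had a median of -0.15 (adjusted p = 2.5e-04, and adjusted p = 0.321 with an estimated correlation), and naive pluripotency genes -0.13 (adjusted p = 0.00206, and adjusted p = 0.0901 with an estimated correlation), in which Gbx2 fell by 1.07 ± 0.13 (below the limit of size without RAH-2 replicate 1 or 3). The methylation machinery (median -0.13, adjusted p = 0.00309) and DNA replication (median -0.11, adjusted p = 0.00702) had adjusted p = 0.0901 and adjusted p = 0.0874 with an estimated correlation. Paternally expressed imprinted genes had a median of -0.08 but a mean of 0.12, with 0 of 17 called.

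What separates the haploid ES cells from haploid germ cells was asked with RahES (n = 6) against round sperm cells (n = 3). Genes that package sperm chromatin, Prm1, Tnp1 and Tnp2, were abundant in round sperm cells and near background in RahES. The protamine gene Prm1 read 64987 ± 5959 against 10.9 ± 10.6 and was at least 648-fold lower in RahES, the transition protein genes Tnp1 (41011 ± 1954) and Tnp2 were at least 410-fold and 358-fold lower. The sperm and testis genes Fabp9, Fam229b, Crisp2, Plaat5 and Adam3a were lower by at least 387-fold, 346-fold, 345-fold, 278-fold and 260-fold. Other genes showed the reverse. The glutathione peroxidase gene Gpx2 (17675 ± 707 against 27.0 ± 15.5), fibronectin (Fn1), the homeobox genes Rhox5 and Crxos1 and the amino acid transporter gene Slc7a3 were at least 177-fold, 144-fold, 137-fold, 130-fold and 128-fold higher. Cd9, Sox2 (6640.0 ± 1454 against 7.03 ± 4.96) and Apoc1 were higher by at least 94.3-fold, 65.1-fold and 46.8-fold. In all, 4539 genes were higher and 3006 lower, 71.6% of 10539, and for 3030 of them only a bound was known. The median over all genes was 0.588, against which the values here are to be read, and 60.2% of called genes were higher. With quantile normalization that share was 54.6% and with median centring 47.6%, so the split between higher and lower depends on the scaling.

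All 32 round spermatid genes were lower in RahES, with a median of -7.77 (-7.08 with bounds, camera adjusted p = 1.9e-11, and adjusted p = 0.00100 with an estimated correlation). The sperm tail genes Odf2 and Tekt2 fell by 4.36 ± 0.06 and 4.91 ± 0.08, and Akap4 was at least 191-fold lower. Spermatocyte genes were lower in 13 of 17 cases and higher in 1 (median -3.73, with bounds -2.91, adjusted p = 0.00219, and adjusted p = 0.0720 with an estimated correlation). Among them Hspa2 fell by 6.10 ± 0.12 and Stag3 by 3.39 ± 0.07, and Meig1 and Ccna1 were at least 229-fold and 82.4-fold lower. Methylation-dependent germline genes were lower in 8 of 10 cases (median -2.82, with bounds -2.46, adjusted p = 0.00256, and adjusted p = 0.0720 with an estimated correlation). Sycp3 fell by 2.41 ± 0.08 (2872 ± 273 against 15361 ± 1677), Smc1b by 3.73 ± 0.14 and Tdrd1 by 4.35 ± 0.17, so their levels in RahES lay far below those of germ cells. Naive pluripotency genes were higher in 18 of 21 cases and lower in 1, with a median of 4.70 (3.78 with bounds, adjusted p = 0.00299, and adjusted p = 0.0674 with an estimated correlation). Tdh rose by 6.77 ± 0.04, Klf2 by 5.85 ± 0.06 (14341 ± 934 against 232 ± 23.6), Rif1 by 4.10 ± 0.06 and the cytokine receptor gene Il6st by 3.78 ± 0.05. Trophoblast-related genes were higher in 11 of 14 cases, with keratin Krt18 at least 58.0-fold higher (median 4.03, with bounds 3.66, adjusted p = 0.00813). DNA replication genes were higher in 21 of 31 cases, with Cdt1 at least 29.0-fold higher (median 3.17, with bounds 2.86, adjusted p = 0.00882), and ERK targets in 16 of 17 (median 3.25, with bounds 2.58, adjusted p = 0.00813). Each of these 3 lists had adjusted p = 0.0720 with an estimated correlation.

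Imprinted genes listed as paternally expressed were higher in RahES in 14 of 17 cases, with Jade1 and Nnat at least 91.6-fold and 14.5-fold higher and Impact and Gnas up 3.56 ± 0.07 and 1.94 ± 0.05 (median 3.10, with bounds 2.17, adjusted p = 0.0334, and adjusted p = 0.126 with an estimated correlation). Mest and Igf2 were at least 5.49-fold and 2.64-fold higher, H19 rose by 4.26 ± 0.07 (3148 ± 711 against 145 ± 8.73) and Meg3 by 2.72 ± 0.12. Maternally expressed genes, with Cobl and Igf2r at least 48.2-fold and 39.4-fold higher, had 9 higher and 4 lower of 23 (median 0.96, with bounds 0.38, adjusted p = 0.487). Markers of blood and macrophages were more abundant in round sperm cells for 13 of 16 genes, such as Aif1 (12639 ± 824 against 7.06 ± 8.57, at least 126-fold), the macrophage receptor gene Mrc1 (at least 12.4-fold) and haemoglobin Hbb (at least 14.7-fold). The list had a median of -2.32 (-1.03 with bounds, adjusted p = 0.00381, and adjusted p = 0.0720 with an estimated correlation). The Leydig cell genes Hsd11b1, Hsd3b1 and Cyp17a1 were also above 100 in round sperm cells, and at least 2.47-fold, 1.82-fold and 1.30-fold lower in RahES, whereas Scarb1 was at least 5.54-fold higher (4 of 7 lower, median -2.36, with bounds -0.87, adjusted p = 0.166). Glycolysis genes were higher in 17 of 23 cases, with Pgk1 up 6.34 ± 0.08 and Gapdh up 4.57 ± 0.06 (median 3.27, with bounds 2.73, adjusted p = 0.0334, and adjusted p = 0.277 with an estimated correlation). Oxidative phosphorylation genes had a median of 0.50, close to that of all genes and -0.17 with median centring (adjusted p = 0.0472, and adjusted p = 0.501 with an estimated correlation). That call ended without RAH-6 replicate 2 (0.0505), round sperm replicate 1 (0.0502) or round sperm replicate 2 (0.0831).

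The same question for the diploid line, DA5-3 against round sperm cells (n = 3 and 3), gave a similar set of genes. Tnp1, Prm1, Fabp9, Tnp2, Crisp2, Plaat5, the linker histone gene Hils1 and Adam3a were lower by at least 410-fold, 648-fold, 387-fold, 358-fold, 345-fold, 278-fold, 272-fold and 260-fold. Slc7a3, Fn1, Rhox5, Gpx2 and the aldo-keto reductase gene Akr7a3 were higher by at least 160.0-fold, 149-fold, 145-fold, 116-fold and 112-fold. The pluripotency factor genes Sall4 and Sox2 were at least 83.9-fold and 80.6-fold higher, and Apoc1 at least 44.9-fold. Tdh, Klf2, Rif1 and Il6st rose by 6.40 ± 0.05, 6.01 ± 0.07, 4.26 ± 0.07 and 4.16 ± 0.06. Sycp3 fell by 4.36 ± 0.09 (732 ± 54.4 against 15361 ± 1677), Smc1b by 5.06 ± 0.16, Odf2 by 5.34 ± 0.07 and Tekt2 by 6.26 ± 0.09, and Taf7l was at least 9.49-fold lower. Igf2 was at least 27.9-fold, Mest at least 7.45-fold and Xist at least 1.45-fold higher, H19 rose by 4.54 ± 0.08 and Meg3 by 3.14 ± 0.13. In all, 4534 genes were higher and 3062 lower, 72.1% of those tested, with a median over all genes of 0.552. The share of higher genes was 59.7%, or 54.1% with quantile normalization and 48.8% with median centring. Round spermatid genes had a median of -7.94 (-7.08 with bounds, adjusted p = 1.2e-11, and adjusted p = 9.4e-04 with an estimated correlation) and naive pluripotency genes 4.83 (4.16 with bounds, adjusted p = 0.00104, and adjusted p = 0.0446 with an estimated correlation). Fibroblast markers were higher in DA5-3 for 19 of 22 genes, with Timp1 up 5.98 ± 0.09 (median 3.96, with bounds 3.55, adjusted p = 0.0181, and adjusted p = 0.450 with an estimated correlation). In RahES the same list had 15 of 22 higher and a median of 2.08 (1.11 with bounds, adjusted p = 0.166).

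X-linked genes stood apart from all other chromosomes in the comparisons with round sperm cells. Sex chromosomes are silenced during meiosis, but whether this or anything else set the X-linked genes apart was not tested. In RahES 247 of 323 X-linked genes were higher and 29 lower, 76.5% higher against 42.0% of autosomal genes, as the cumulative plot of fold changes shows. Their median was 2.89 against 0.52 for autosomal genes, a difference of 2.37 (medians with bounds 2.42 and 0.31, adjusted p = 5.6e-08, and adjusted p = 6.1e-05 with an estimated correlation). In DA5-3 the median was 2.74 against 0.50, a difference of 2.24 with 75.9% of X-linked genes higher (medians with bounds 2.17 and 0.31, adjusted p = 6.0e-08, and adjusted p = 6.2e-05 with an estimated correlation). Among X-linked genes the helicase gene Ddx3x rose by 5.05 ± 0.06 in RahES, and Eif2s3 and Kdm5c were at least 60.9-fold and 12.9-fold higher. The Y-linked Eif2s3y, a relative of Eif2s3, read 2616 ± 577 in round sperm cells, 21.8 ± 7.14 in DA5-3, 6.65 ± 4.95 in RAH-2 and 1.18 ± 0.225 in RAH-6. The probe set named for the Y-linked Uty read 1898 ± 86.0 in RahES and 65.6 ± 3.07 in round sperm cells. Its gene is uncertain because it may measure an X-linked relative, which was not tested. RahES and DA5-3 shared 4218 higher and 2833 lower genes (1953 and 873 if independent) with 7 in opposite directions. Their fold changes correlated at r = 0.982, against 0.577 in simulated groups without change, with covariances of 8.10 and 0.0174, a difference of 8.08. This simulation too held only the spread between cultures or samples of a group. The excess therefore cannot tell a trait shared by the ES lines from a trait of the round sperm cells. Part of the overlap above that of independent calls may come from the shared controls, and 3 control arrays cannot be split into separate sets.

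**Figure D4:**
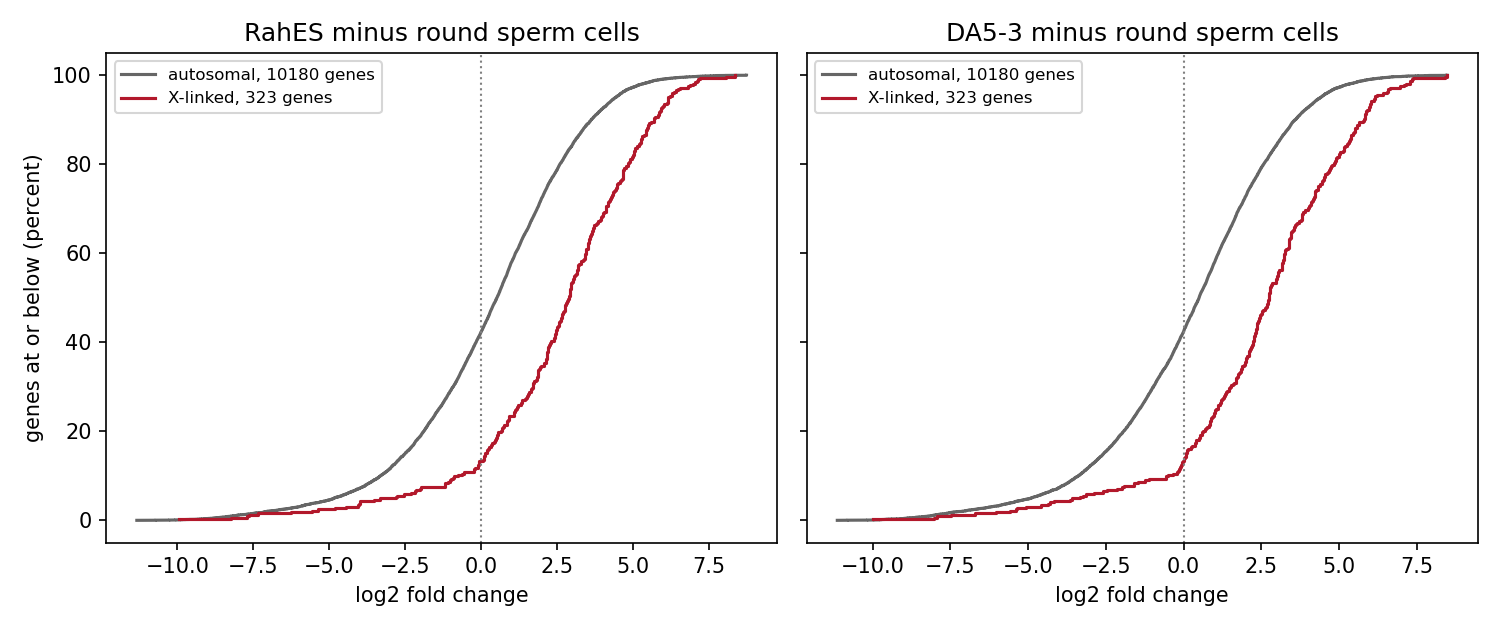
Cumulative percent of genes against log2 fold change for 10180 autosomal and 323 X-linked genes, RahES against round sperm cells and DA5-3 against round sperm cells.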

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

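Of the tests in this part, the one of RNA quality was planned, and those of fibroblast-like cells and of round sperm cell RNA were chosen after the results were seen. RAH-6 and RAH-2 differed from DA5-3 by unequal amounts for 5 of the named genes, tested in limma as the difference between the lines. The hormone gene Adm, below 100 on all DA5-3 arrays, was at least 3.22-fold higher in RAH-6 and at least 9.54-fold higher in RAH-2, and between these lines the difference was -1.52 ± 0.11 (adjusted p = 9.7e-06). S100a1 rose by 3.79 in RAH-6 and 2.66 in RAH-2, a difference of 1.13 ± 0.35 (adjusted p = 0.0419). Lower in RAH-2 than in RAH-6 were Col5a2 (-3.24 in RAH-6 and -5.49 in RAH-2, difference 2.25 ± 0.58, adjusted p = 0.0183), Vim (-2.21 and -3.66, difference 1.45 ± 0.45, adjusted p = 0.0408) and Ccdc80 (-3.24 and -4.34, difference 1.10 ± 0.32, adjusted p = 0.0332). The RAH-2 cultures were uneven: Col5a2 read 1117 on replicate 2 against 97.9 and 151, and Ccdc80 167 against 35.1 and 68.7. The calls of Col5a2 and Vim ended without RAH-2 replicate 1 or 3, so a stable difference between the lines is not shown for them. Of 3141 tested probe sets that carry no gene name, 113 were higher and 146 lower in RahES than in DA5-3, 8.25% of them, and these appear in none of the gene comparisons. Single arrays were not tested against the others of their group.

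Fibroblast marker genes were far lower in RahES than in DA5-3, 14 of 22 of them by 1.11 to 4.39. Fewer fibroblast-like cells in the RahES cultures stay open as a source: 13 of the 14 genes were highest in RAH-2 replicate 2 among the RAH-2 arrays, but so were 70.1% of the other lower genes. That array lies nearest to DA5-3 on PC1 of the ES cells (13.6 against 20.4 and 19.8). PC1 was computed from the same genes. It cannot tell whether fibroblast-like RNA moved that array or whether lower genes of any kind tend to be highest there. RNA quality, as the actin 3' to 5' ratio, predicted a difference of 0.19 (95% interval -1.39 to 1.78) for these 14 genes, where -2.70 was observed. If that slope, found within lines, also holds between them, a part of the difference stays open but not the whole. Whether the lines differ in feeder cells carried along or in differentiated cells of their own, and whether line or ploidy matters, was not tested and stays open.

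Igf2 was at 271 in RahES and 2793 in DA5-3 on the single probe set used. H19 and Meg3, which lie beside paternally expressed genes, were near the DA5-3 level. H19 and Meg3 moved by only -0.28 and -0.42, against a median of -1.94 for all 22 measured fibroblast markers. Of these markers 14 were lower, 1 was higher and 7 were not called. The median of -2.56 for the 14 lower ones is that of genes picked for being lower. If the fall of the markers reflects fewer fibroblast-like cells, which stays open, the values argue against such cells as the source of most H19 or Meg3 RNA. Fibroblast-like cells could carry part of the Igf2 difference. Extending the trend of Igf2 within the lines to the marker level of DA5-3 gave 514 (95% interval -485 to 1513), below the 2793 measured, but without RAH-2 replicate 2 the interval ran from -10051 to 3525, so this cannot be told apart from a difference between the lines. Igf2 is listed as paternally expressed, and H19 and Meg3 as maternally expressed. Low Igf2 beside abundant H19 and Meg3 thus runs opposite to the imprint of a paternal genome, for these 3 genes. Called genes of the 2 imprinted lists went both ways. Whether imprints were altered, and any other role of the purely paternal genome in the Igf2 level, stays open, since allele-specific RNA and DNA methylation were not measured on these arrays.

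Of 8 germline genes that depend on DNA methylation for silencing, Sycp3, Smc1b and Taf7l were called higher in RahES than in DA5-3, and the list was not called with an estimated correlation (adjusted p = 0.293). RNA of round sperm cells carried into the cultures would have to make up 14.6% of the RNA (median of the 3 genes) and would bring spermatid RNA with it. The 32 spermatid genes rose by a median of only 0.466% of what that share predicts, and Prm1 reached at most 25.2 on a RahES array where 9508 was predicted, which argues against round sperm cells as the source. Earlier germ cells were not tested as a source, and what raised these genes stays open, since DNA methylation was not measured on these arrays and line and ploidy were not tested apart.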

How the results depend on the processing

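The alternative that leaves out DA5-3 replicate 1, RAH-2 replicate 2 and round sperm replicate 1 was chosen after seeing the data, and the others were planned. Of the results that answer a comparison, 426 values under the alternatives were the same, 13 moved by over 1.5 times and 2 became stronger. Of the values for named genes 8998 were the same, 22 became stronger, 101 weaker and 8 reversed, and for the other gene lists 895 were the same and 33 weaker. Offset 64 in place of 16, which shrinks folds at low signal, gave 210 higher genes for RahES against DA5-3 (346 with 16), 177 for RAH-2 against DA5-3 (312), and 17 higher and 9 lower for RAH-6 against RAH-2 (56 and 18). Without a filter on low signals, which adds genes near background, 454 genes were lower for RAH-2 against DA5-3 (297) and 87 higher for RAH-6 against RAH-2. A filter at 200, which tests fewer genes, gave 184 lower for RAH-2 against DA5-3, 178 lower for RahES against DA5-3 (268) and 34 higher for RAH-6 against RAH-2. Naive pluripotency genes in RahES against DA5-3 passed the threshold without the filter (median -0.21, adjusted p = 0.0444) and with the filter at 200 (-0.24, adjusted p = 0.03549), and the cause was not tested. Leaving out each array in turn gave 37 to 110 higher and 11 to 17 lower genes for RAH-6 against RAH-2, 341 to 369 higher and 257 to 278 lower for RahES against DA5-3, and 4522 to 4568 higher and 2994 to 3016 lower for RahES against round sperm cells. Leaving out DA5-3 replicate 1, RAH-2 replicate 2 and round sperm replicate 1 together gave 114 higher genes for RAH-6 against RAH-2. This was close to the 110 without RAH-2 replicate 2 alone. The direction reversed only for uncalled genes near 0. For RAH-6 against DA5-3, H19 was -0.0469 with median centring, -0.0146 without those 3 arrays and -0.0441 to 0.0638 leaving out each array. Meg3 was 0.0353 with the mean over probe sets. For RAH-2 against DA5-3, Sox2 was 0.0488 with quantile normalization and -0.124 to 0.0615 leaving out each array. The cause of these was not tested. Fibroblast markers in RahES against DA5-3 stayed under the threshold at the preset correlation in all alternatives run, with adjusted p from 1.0e-06 (without RAH-2 replicate 2) to 0.00532 (median centring). The replicate numbers showed no sign of pairing: arrays of different groups with the same number correlated at -0.0886 to 0.0586 after group means were removed. Whether such cultures were handled together is not known. A replicate block moved none of the 482 results for named genes across the threshold and ended only the list calls of p53 targets in RAH-2 against DA5-3 (adjusted p = 0.0565) and of oxidative phosphorylation in RahES against round sperm cells (0.0526). Offset 64 ended 25 calls among the 482 results for named genes, the most of the settings run. Signal over background limits folds: for 202 of 614 called genes in RahES against DA5-3 only a bound was known.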

Other observations

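The counts of splits given in this part were planned. The joint removal of DA5-3 replicate 1, RAH-2 replicate 2 and round sperm replicate 1 was chosen after the data were seen. The tubulin gene Tubb5 rose by 6.92 ± 0.05 in RahES (n = 6) against round sperm cells (n = 3), from 97.7 ± 4.05 to 13741 ± 678, and the transferrin receptor gene Tfrc by 5.70 ± 0.06. Housekeeping genes were higher in 9 of 14 cases and lower in 1 (median 2.07, camera adjusted p = 0.0334, and adjusted p = 0.204 with an estimated correlation). The medians of other lists against round sperm cells are to be read beside that value too. The maintenance methylation genes Dnmt1 and Hells were at least 32.2-fold and 16.4-fold higher and Uhrf1 rose by 3.41 ± 0.08, and 14 of 19 genes of the methylation machinery were higher (median 2.81, with bounds 2.72, camera adjusted p = 0.0334, and adjusted p = 0.0781 with an estimated correlation). Cholesterol synthesis genes were higher in 14 of 21 cases, with Fasn up 5.65 ± 0.13 and Acly up 4.62 ± 0.04 (median 2.43, adjusted p = 0.0418, 0.0559 without those 3 arrays, and adjusted p = 0.0897 with an estimated correlation). Targets of p53 were higher in 17 of 21 cases, with Ccng1 up 4.98 ± 0.05, but Mdm2, which restrains p53, fell by 2.52 ± 0.05 (3186 ± 149 against 18276 ± 626). The list had a median of 2.99 (1.95 with bounds, adjusted p = 0.0328, and adjusted p = 0.0720 with an estimated correlation).

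The neuronal genes Stmn2 (5644 ± 459 against 22.2 ± 5.54) and Nefl were at least 56.3-fold and 19.96-fold higher in RahES than in round sperm cells, while Map2 was at least 6.12-fold lower. Of 9 Wnt targets 7 were higher, such as Lef1, up 1.67 ± 0.07, and 1 was lower, the inhibitor gene Wif1, which fell by 6.25 ± 0.15 from 7791 ± 357 to 87.6 ± 16.3 (list median 2.49, with bounds 1.67, adjusted p = 0.166). Mitosis genes went both ways, with Chek1 at least 20.5-fold higher, Cdk1 up 1.60 ± 0.05 (its call and that of Lef1 ended with median centring) and the kinase gene Plk1 down by 1.44 ± 0.06 (11 of 29 higher, 5 lower, median 0.40, close to the 0.588 of all genes). Sertoli cell genes had 5 higher and 6 lower of 14, with a median of -0.04 and a mean of 0.40, the cathepsin gene Ctsl rising by 5.17 ± 0.07 and Aard at least 8.34-fold lower.

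Other splits of the arrays into groups of the same sizes were counted for each comparison, with the ES lines of RahES pooled. Each fit used only the arrays of its comparison, so the counts of the real split differ from those given above. For RahES against DA5-3 only 1 of 84 splits, the real one, called as many genes (611, highest other split 60). For RahES against round sperm cells it was also 1 of 84 (7476, highest other 0). The splits treat cultures of 1 line as independent, so they cannot exclude a chance difference between lines. With 3 arrays against 3, the 10 splits are too few for a share under 0.05. There the real split called 581 genes for RAH-2 against DA5-3, 697 for RAH-6 against DA5-3, 53 for RAH-6 against RAH-2 and 7443 for DA5-3 against round sperm cells, and the highest other split called 0 in each.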
